A study of Mus musculus with 8 samples.

How the data were processed

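Hippocampal RNA was measured in 4 libraries of wild-type mice (WT) and 4 libraries of mice hemizygous for the Tg(Camk2a-cre)2Gsc transgene (Cre), all 9 weeks old and on the C57BL/6J strain per the labels. In this line, also called CamiCre, regulatory DNA of Camk2a drives the Cre recombinase in forebrain excitatory neurons. Per the labels' protocols, poly(A) RNA was selected from total RNA, libraries were made with a directional kit that keeps the strand of the transcript, and all were pooled for paired-end sequencing of 150 bases in a single NovaSeq lane. The labels give each library a genotype and a number, and do not say whether each library came from a different animal. The p-values therefore measure the spread between these libraries.

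The deposited count table holds whole-number counts per gene symbol and library, not normalized, as the authors made them. Per the submitters' processing notes, STAR 2.6.1d, featureCounts and edgeR 3.11 were used with the mouse genome GRCm38. The featureCounts version, the annotation release and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of overlapping genes on opposite strands, or reads that run past the end of a gene into its neighbour, cannot be assigned with certainty. The authors also deposited a table of their own comparison, with a log2 fold change, a signed fold, an average abundance on a log2 scale, the same abundance on a linear scale (a smoothed score rather than the CPM of a library) and a p-value per gene. The labels do not say whether the authors' deposited p-value is adjusted. It was under 0.05 for 501 genes, near the 480 with an unadjusted p under 0.05 in the edgeR exact test run here. That count argues against an adjusted value. Benjamini-Hochberg adjustment was applied to the deposited p-value here. The sign of the deposited fold change is Cre over WT, as read from Syt2 and Slc6a7 in the count table.

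The count table has 46078 gene entries, of which 272 repeat an earlier symbol and 27 carry a symbol that had been turned into a date. Both kinds were kept as separate entries. No entry lacked a gene name, so all counts entered the library totals. A total of 26369 genes had at least 1 count. Library totals ran from 21339996 to 27826871 counts. Genes with enough counts were kept by filterByExpr (minimum count 10, minimum total 15), which left 15859 genes holding 99.9% of the counts in each library. Normalization used the trimmed mean of M values (TMM), with factors from 0.988 to 1.01. The share of counts in mitochondrially encoded genes was 3.03% to 3.74%, and the most abundant gene, mt-Co1, took 1.02% to 1.25% of a library. At this depth the median standard error of a log2 fold change was 0.07, and the 90th percentile was 0.28. A gene with 0 counts in a library could still have had up to 0.108 to 0.141 CPM (counts per 1000000 normalised library counts) there, the level of 3 counts. Intervals and such limits cover counting error only where they come from counts, because reads without molecular identifiers are not independent molecules.

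Before the data were examined, the design, the gene lists, the marker lists, the rule for naming genes and most alternatives were fixed. The comparison of Cre with WT used edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, no covariate, 2-sided) with Benjamini-Hochberg adjustment over all 15859 genes and a threshold of 0.05. Fold changes were Cre over WT. Levels are normalised CPM, given as mean ± SD over 4 libraries. For single genes, an exact permutation test over all splits of the 8 libraries was also run on log2 CPM, 2-sided, and its smallest possible p is 0.0286. The 15 gene lists and 18 marker lists were tested together with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the 33 lists. The same lists were tested with a correlation estimated from the data, and with fry, which asks whether a list moves one way on balance and not whether it differs from other genes. Named genes are Syt2 and Camk2a, the genes with the largest changes past the threshold (up to 10 in each direction) whose groups did not overlap and whose mean log2 CPM was at least 0, synaptotagmins, neighbours of Camk2a, and the members of each list with the smallest p (up to 4 for lists past the threshold). Pm20d1, Hes5, Malat1, Col6a4, Xist, Ddx3y and the genes next to Syt2 fall outside that rule and were chosen after their values were seen.

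Positions are from GENCODE mouse release M21, which uses GRCm38, matched to the count table by unambiguous gene symbol. Of the tested genes, 15061 (95.0%) had a position. Called genes within 1 Mb of Syt2 and of Camk2a were compared with the rest by Fisher's exact test, called genes per chromosome likewise with adjustment over chromosomes, and the largest number of called genes in any 5 Mb window was compared with 10000 random draws of as many tested genes. Every pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 3.40 to 10.0). Each library counted as 1 replicate, although this spread does not show that each came from a different animal.

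The alternatives were DESeq2 size factors or library size alone in place of TMM, no low-count filter or a filter of CPM 1 in 4 libraries, DESeq2 1.42.0, limma voom, a minimum fold of 1.2, other window sizes, another prior count, and leaving out each library in turn. A fit with the replicate number as a replicate block was among them, and its count of 6 genes is described with the other alternatives. The edgeR exact test, the summing of entries that share a symbol and a 10 Mb window were added after the data were seen. The steps were tested on simulated counts drawn from the means and library sizes of these 8 libraries (15693 genes, 50 genes changed at each fold). The test recovered 52% of genes changed 1.25-fold, 84% at 1.5-fold, 76% at 2-fold and 94% at 4-fold, with 6 false calls among 159. The Benjamini-Hochberg adjustment is less strict with 159 calls than with the 5 calls of the real comparison. These shares may therefore overstate the recovery in the real comparison. In simulated lists, a list shifted by 0.5 on the log2 scale was recovered by camera. Genes were drawn independently there, so this step does not show how camera behaves for lists whose members move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads of the transgene itself, exon usage and sequence variants were not analysed here. The values of 1 gene are not reported here.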

Results

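RNA-seq counts were obtained from hippocampus, the forebrain region whose principal neurons express Camk2a at high levels. The 8 libraries comprised 4 from WT mice and 4 from Cre mice of the Tg(Camk2a-cre)2Gsc line, all 9 weeks old. The WT libraries held 24289522 to 26950207 counts and the Cre libraries 21339996 to 27826871. The comparison asked which hippocampal transcripts differ in mice that carry this Cre transgene when no floxed target gene is involved. The series is titled for Syt2, so this gene is described first.

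Syt2, which encodes a fast calcium sensor for synaptic vesicle release, was 4.97-fold higher in Cre hippocampus (95% confidence interval 4.43 to 5.57). Its level was 35.4 ± 4.10 CPM in WT and 176 ± 12.2 CPM in Cre (SD, n = 4 each), and the 4 Cre libraries (164 to 188 CPM) all lay above the 4 WT libraries (32.8 to 41.5 CPM). Slc6a7, which encodes a brain L-proline transporter, was 4.28-fold higher (3.93 to 4.66), from 72.7 ± 4.72 to 311 ± 18.99 CPM. Arsi, a sulfatase gene, rose from 1.06 ± 0.23 to 11.2 ± 3.30 CPM. Cdx1, which encodes a homeobox factor of the intestinal epithelium, gave 81 counts over the Cre libraries and 1 count over the WT libraries, a ratio of 85.4 after correction for library size (exact interval 14.9 to 3413, counting error only). Mcm6, which encodes a subunit of the replicative DNA helicase, fell from 15.5 ± 2.07 to 9.28 ± 0.69 CPM.

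These 5 genes, 4 higher and 1 lower in Cre, were the only ones of 15859 past the threshold by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The log2 fold changes were 2.31 for Syt2 (SE 0.08, adjusted p = 2.48e-09), 2.10 for Slc6a7 (SE 0.06, adjusted p = 4.01e-10), 3.38 for Arsi (SE 0.23, adjusted p = 1.33e-05) and -0.74 for Mcm6 (SE 0.10, adjusted p = 0.0176) with this test. For Cdx1 the fitted value was 5.81 (SE 0.60, adjusted p = 0.00124 by the same edgeR test), which depends on the prior count because WT was near 0. In each of the 5 genes the groups did not overlap, which gave the smallest p an exact permutation test can reach with 4 libraries against 4, 0.0286. At an unadjusted p under 0.05 there were 555 genes, 325 higher and 230 lower, where 793 would be reached by chance alone. The groups did not overlap in 367 genes (2.31%), against 2.86% by chance. The Mcm6 call was lost when WT replicate 1 (adjusted p = 0.0801), Cre replicate 1 (0.0777), Cre replicate 2 (0.0883) or Cre replicate 3 (0.125) was left out, with log2 fold changes from -0.79 to -0.66 over all 8 such edgeR fits. It was also lost against a minimum fold of 1.2 (adjusted p = 0.147), and its adjusted p over all alternatives ran from 4.24e-08 to 0.147.

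**Figure D1:**
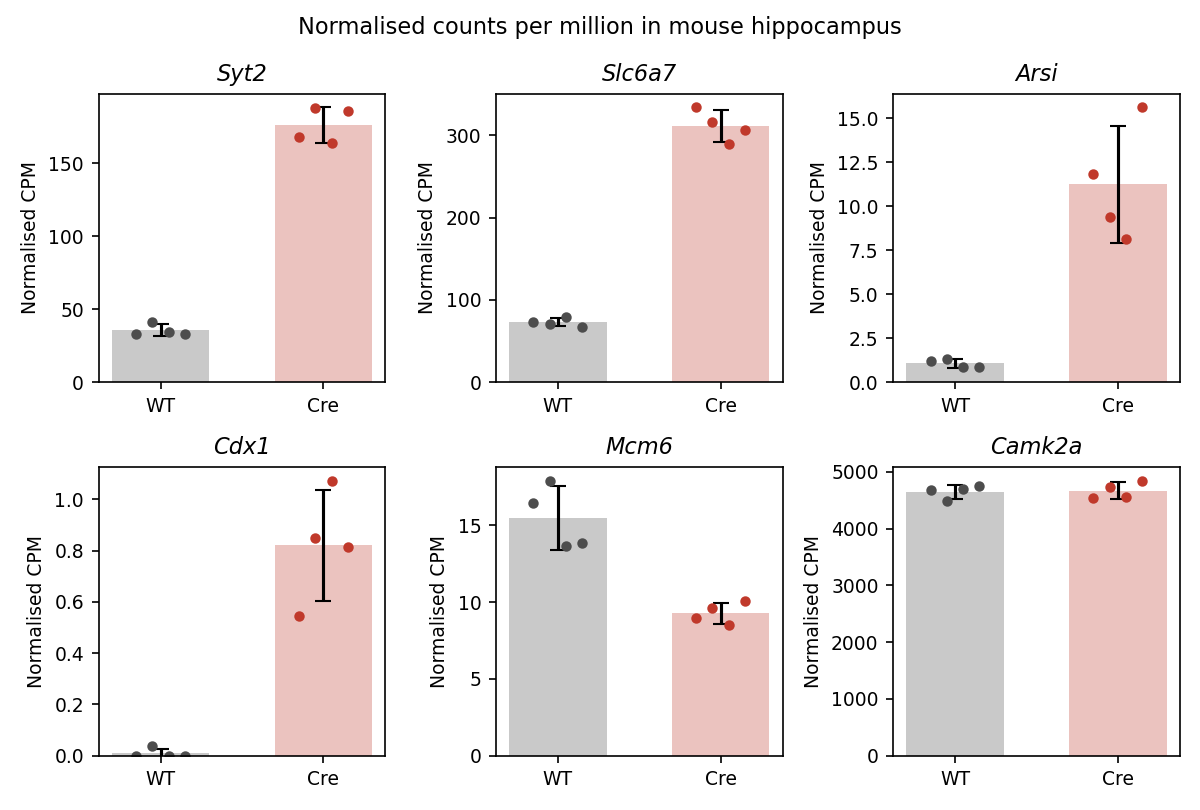
Normalised CPM (vertical axes, linear, from 0) of 6 genes in WT and Cre hippocampus, with 1 point per library and bars and error bars for the mean ± SD of 4 libraries. Syt2, Slc6a7, Arsi and Cdx1 are higher in every Cre library, Mcm6 is lower in every Cre library, and Camk2a overlaps at means of 4652 and 4669 CPM.

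Syt2 lies on chromosome 1 at 134646677 to 134762593 (GRCm38, plus strand). Among the 16 synaptotagmins measured, Syt2 rose and the other 15 did not pass the threshold. Of those, 13 had fold changes below 0 and 2 above, from -0.32 to 0.12 on the log2 scale, and 2 had an unadjusted p under 0.05. Syt1, the main calcium sensor of forebrain synapses and the named member with the highest CPM, stood at 1496 ± 37.4 CPM in WT and 1427 ± 99.5 CPM in Cre (log2 fold change -0.07, SE 0.04). Syt9 had 8.08 ± 0.90 CPM in WT and 6.49 ± 0.76 in Cre (log2 fold change -0.32, SE 0.11), and Syt10 6.61 ± 0.51 and 5.50 ± 0.58 (log2 fold change -0.26, SE 0.11), neither past the threshold. Adjusted over the list alone, Syt2 was again the only member past it. The list as a whole did not differ from other genes by camera (adjusted p = 0.346; direction down, median -0.04, mean 0.08), while fry gave a rise (adjusted p = 0.0235) in which Syt2 alone has a large weight.

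The genes beside Syt2 did not share its change. Kdm5b, a histone demethylase gene 11.4 kb before Syt2, had a log2 fold change of 0.05 (SE 0.05). Ppp1r12b, a myosin phosphatase subunit gene on the minus strand whose annotated span overlaps the end of Syt2, had -0.03 (SE 0.04), so any reads exchanged with Syt2 left its level at 161 ± 6.03 CPM in WT and 158 ± 4.03 CPM in Cre. Within 1 Mb of Syt2, 0 of 28 other genes passed the threshold by edgeR's quasi-likelihood test and 0 by DESeq2 or limma voom. At an unadjusted p under 0.05 there were 2, and the median log2 fold change was -0.01.

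Camk2a, which encodes the alpha subunit of calcium/calmodulin-dependent protein kinase II, did not differ between the groups at 4652 ± 120 CPM in WT and 4669 ± 149 CPM in Cre (SD, n = 4 each). Its log2 fold change was 0.01 (SE 0.03, 95% confidence interval -0.06 to 0.07), so a rise above 4.96% or a fall below -4.00% lies outside the interval. The gene spans 60925618 to 60988152 on the plus strand of chromosome 18. Arsi (60911780 to 60918561, plus strand) ends 7.06 kb before it. Slc6a7 (60995380 to 61014222, minus strand) begins 7.23 kb after it, and Cdx1 (61018862 to 61036199, minus strand) 30.7 kb after it. The 3 genes that rose and Camk2a thus fill 124 kb in which Camk2a alone, among the protein-coding genes tested, did not change.

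The next tested genes outward did not pass the threshold. Tcof1, a nucleolar factor gene 76.6 kb before Camk2a, had a log2 fold change of 0.04 (SE 0.06), and Pdgfrb, a growth factor receptor gene 57.0 kb after it, had 0.003 (SE 0.11). Csf1r, a receptor of microglia 112 kb after Camk2a, stood at 87.7 ± 1.91 CPM in WT and 99.0 ± 9.82 in Cre (log2 fold change 0.17, SE 0.06). It passed only when adjusted over the list alone (adjusted p = 0.0446 by edgeR). Csf1r is also in the list of microglia markers, where it did not pass adjusted over the list alone (adjusted p = 0.0738 by edgeR) and all 13 members lay above 0 (median 0.20). Cre replicate 1 had 113 CPM of Csf1r, against 91.5 to 95.8 CPM in the other Cre libraries and 84.9 to 89.1 CPM in WT. Of the 14 measured genes in the list of Camk2a neighbours, 3 rose over all genes and 4 passed when adjusted over the list alone (Arsi, Slc6a7, Cdx1 and Csf1r). The list differed from other genes by camera (adjusted p = 1.46e-04; adjusted p = 0.118 with an estimated correlation) with a median of 0.01 and a mean of 0.79, so the call rests on the 3 genes. Within 1 Mb of Camk2a, 3 of 28 other genes passed, against 2 of 15032 elsewhere (Fisher's exact p = 5.74e-08).

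Slc6a7 rose by a smaller factor than Arsi, with a log2 difference of -1.28 (SE 0.24; exact permutation p = 0.0286, the smallest possible, n = 4 per group). On the CPM scale Slc6a7 gained 239 CPM (SE 9.78), Arsi 10.2 CPM (SE 1.66) and Cdx1 0.81 CPM (SE 0.11). CPM are not corrected for transcript length, so these gains do not compare amounts of transcript between genes. Chromosome 18 held 3 of its 430 tested genes past the threshold (Fisher's exact adjusted p = 0.00443 over chromosomes), and chromosome 1 held 2 of 973 (adjusted p = 0.366). The 3 genes in 1 window of 5 Mb had a 1-sided permutation p = 4e-04, from 10000 random draws of as many tested genes with the observed case counted in.

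**Figure D2:**
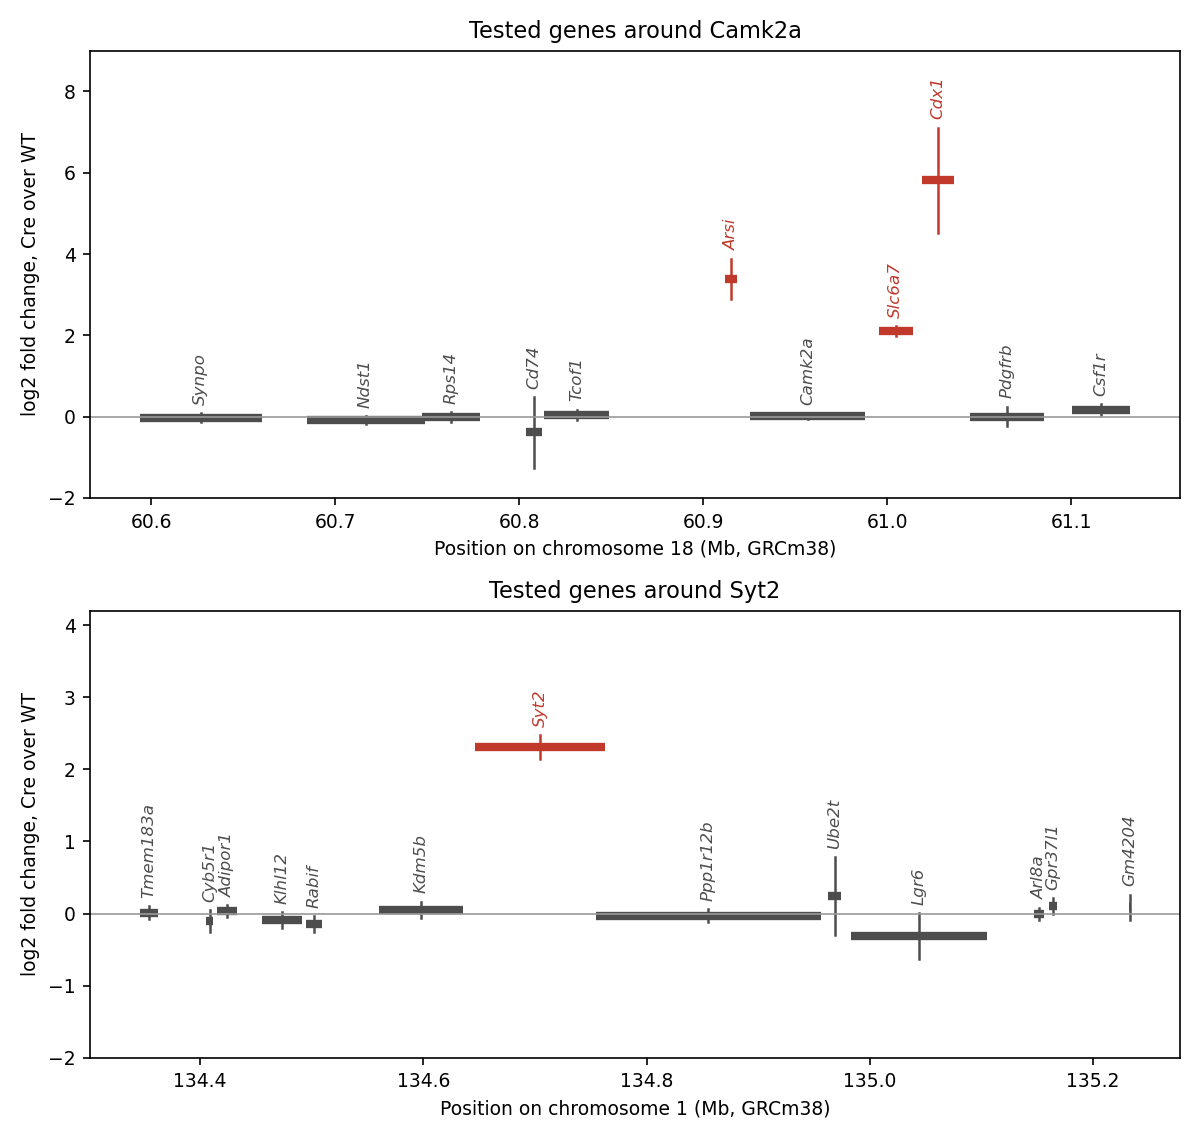
Log2 fold change of Cre over WT (vertical axes) against position in Mb (horizontal axes, GRCm38) for tested genes around Camk2a on chromosome 18 and Syt2 on chromosome 1; thick bars span each gene, thin lines are 95% confidence intervals, red marks genes past adjusted p 0.05, and microRNA genes inside Camk2a are left out. Arsi, Slc6a7 and Cdx1 lie above 0 on both sides of Camk2a, which stays at 0.01, and Syt2 stands alone at 2.31.

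Mcm6 lies on chromosome 1 at 128331590 to 128359664 (minus strand), 6.32 Mb before Syt2. Between both lies Pm20d1, which encodes an enzyme of N-acyl amino acid metabolism, 2.85 Mb before Syt2. Pm20d1 had 1.77 ± 0.44 CPM in WT and 4.19 ± 1.29 CPM in Cre, with no overlap between the groups, and a log2 fold change of 1.24 (SE 0.24) that did not pass (adjusted p = 0.420 by edgeR's quasi-likelihood test). Hes5, a Notch target gene on chromosome 4, had 11.0 ± 0.43 CPM in WT and 7.95 ± 0.68 CPM in Cre, a log2 fold change of -0.47 (SE 0.08) that did not pass by the same test (adjusted p = 0.261). Both passed with DESeq2 (adjusted p = 0.00330 and 0.0381). Over all alternatives the adjusted p ran from 0.00211 to 0.9997 for Pm20d1 and from 0.00258 to 0.9999998 for Hes5. The authors' deposited table, made from the same libraries and so not independent, held 7 genes past 0.05 after Benjamini-Hochberg adjustment of its p-values, 5 higher and 2 lower. They were the 5 genes above with Pm20d1 (log2 fold change 1.24 in the authors' deposited table) and Hes5 (-0.47). Across 15839 genes in both, its log2 fold changes and those computed here had a Spearman correlation of 0.9999, as a description across genes, which are not independent replicates.

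Of 25 activity-regulated immediate early genes, 22 had fold changes above 0, with a median of 0.25 on the log2 scale. The list differed from other genes by camera (adjusted p = 3.11e-06), in all 8 fits that left out 1 library, but not with an estimated correlation (adjusted p = 0.541 with an estimated correlation). Those 8 fits kept the preset inter-gene correlation of 0.01, against an estimate of 0.24 from the data. The per-library means overlapped, at 4.99 to 5.27 log2 CPM in WT and 5.13 to 5.45 in Cre. Of the members, 0 passed over all genes by edgeR's quasi-likelihood test or by DESeq2, with 7 at an unadjusted p under 0.05, all higher. Adjusted over the list alone, 2 passed, Fos and Gadd45b. Fos, a transcription factor gene induced by neuronal firing, stood at 17.9 ± 3.22 CPM in WT and 26.5 ± 5.91 CPM in Cre (log2 fold change 0.58, SE 0.15), with WT replicate 3 at 22.6 CPM inside the Cre range. Arc, which encodes a postsynaptic regulator of AMPA receptors, stood at 172 ± 33.0 and 232 ± 51.5 CPM (log2 fold change 0.43, SE 0.15), and Egr2, a zinc finger factor gene, at 4.12 ± 1.40 and 6.87 ± 2.32 CPM (log2 fold change 0.75, SE 0.25).

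The glucocorticoid-responsive list also lay higher by camera (14 genes, median 0.12, adjusted p = 0.0268; adjusted p = 0.791 with an estimated correlation). Its leading members were the metallothionein genes Mt1 (94.9 ± 7.14 CPM in WT, 112 ± 8.37 in Cre) and Mt2 (63.1 ± 8.41 and 80.0 ± 8.79), the 2 that passed when adjusted over the list alone and that did not pass over all genes. Metallothioneins bind metal ions and respond to metals as well as to steroids. The call was lost without WT replicate 1 (adjusted p = 0.729), WT replicate 3 (0.0574), Cre replicate 3 (0.164) or Cre replicate 4 (0.331).

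Of the lists of channel and synapse genes, 3 passed by camera with medians below 0, and 0 of these passed with an estimated correlation. Voltage-gated calcium channels (camera adjusted p = 0.485), GABA genes (0.106) and synaptotagmins (0.346) did not pass. Of 28 potassium and sodium channel genes, 23 had fold changes below 0 (median -0.05; camera adjusted p = 0.00220, adjusted p = 0.541 with an estimated correlation), and the call was lost without Cre replicate 3 (adjusted p = 0.143). Kcnb2, a voltage-gated potassium channel gene, had 31.8 ± 1.49 CPM in WT and 28.6 ± 1.90 in Cre (log2 fold change -0.15, SE 0.06), and the astrocytic channel gene Kcnj10 had 166 ± 3.10 and 182 ± 8.53 CPM, against the direction of the list (0.14, SE 0.04). The vesicle release machinery (39 genes, 28 below 0, median -0.03) had a camera adjusted p = 0.0364 (adjusted p = 0.716 with an estimated correlation), lost without WT replicate 3 or 4 (adjusted p = 0.203 and 0.0901) or Cre replicate 1, 3 or 4 (0.301, 0.221 and 0.0838). Its smallest p belonged to Sv2c, a vesicle protein gene with a log2 fold change of 0.27 (SE 0.09), against the direction of the list, and the abundant vesicle protein gene Syp had -0.06 (SE 0.03). Glutamate receptor and postsynaptic genes (33, of which 24 below 0, median -0.03), led by Grm5 at -0.10 (SE 0.04), had a camera adjusted p = 0.0478 (adjusted p = 0.5999 with an estimated correlation). That call was lost without WT replicate 2 or 3 (adjusted p = 0.117 and 0.204) or Cre replicate 1 or 3 (0.303 and 0.143). In these 3 lists 0 members passed over all genes (edgeR or DESeq2) or adjusted over the list alone, and 3, 1 and 1 had an unadjusted p under 0.05, in the order given.

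By camera, markers of 3 glial cell types lay higher in Cre beside these lists. All 13 microglia markers had fold changes above 0 (median 0.20; camera adjusted p = 2.70e-07, adjusted p = 0.541 with an estimated correlation). Complement genes C1qb (30.9 ± 1.12 CPM in WT, 38.8 ± 6.94 in Cre) and C1qc (27.7 ± 1.52 and 33.2 ± 5.61) and the protease gene Ctss (37.6 ± 1.27 and 46.4 ± 11.5) were among those with the smallest p. Of 12 astrocyte markers, 11 lay above 0 (median 0.09; camera adjusted p = 0.00220, adjusted p = 0.541 with an estimated correlation), among them the glutamate transporter genes Slc1a2 (2974 ± 108 and 3210 ± 104 CPM) and Slc1a3 (563 ± 13.7 and 600 ± 22.2 CPM) and the filament gene Gfap (417 ± 30.7 and 537 ± 169 CPM). The microglia and astrocyte calls stood in all 8 fits that left out 1 library. Those fits kept the preset inter-gene correlation of 0.01, against estimates from the data of 0.63 for microglia and 0.21 for astrocytes. They therefore do not test that setting. All 12 oligodendrocyte markers lay above 0 (median 0.11; camera adjusted p = 0.00595, adjusted p = 0.773 with an estimated correlation), with the myelin genes Mobp (625 ± 59.4 and 720 ± 75.4 CPM) and Mal (159 ± 13.3 and 182 ± 22.4 CPM). That call was lost without WT replicate 1 (adjusted p = 0.0753), Cre replicate 1 (0.303) or Cre replicate 2 (0.145). In these 3 lists 0 markers passed over all genes (edgeR or DESeq2) or adjusted over the list alone, with 6 microglia, 4 astrocyte and 2 oligodendrocyte markers at an unadjusted p under 0.05. Cre replicate 1 carried the highest mean of each, for microglia 5.08 log2 CPM against 4.66 to 4.68 in the other Cre libraries and 4.48 to 4.65 in WT. The per-library means overlapped for astrocytes (7.55 to 7.63 log2 CPM in WT, 7.61 to 7.77 in Cre). They also overlapped for oligodendrocytes (6.85 to 6.95 in WT, 6.77 to 7.24 in Cre), where Cre replicate 4 was the lowest of all 8 libraries.

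Choroid plexus markers were high in a single library. WT replicate 1 had a mean of 4.73 log2 CPM over 8 markers, against 0.15 to 0.98 in the other WT libraries and 0.37 to 1.44 in Cre. Ttr, the transthyretin gene of choroid plexus epithelium, had 23719 counts in WT replicate 1 and 41 to 320 in the other 7 libraries, and its fitted log2 fold change of -5.19 (SE 1.63) turned to 0.39 without that library. Clic6, a chloride channel family gene, went from -3.07 to 0.67 likewise, and neither passed over all genes. The list was past the threshold by camera (median -2.30, adjusted p = 0.0354; adjusted p = 0.791 with an estimated correlation) and was lost without WT replicate 1 (adjusted p = 0.535), Cre replicate 2 (0.0892), Cre replicate 3 (0.103) or Cre replicate 4 (0.102).

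**Figure D3:**
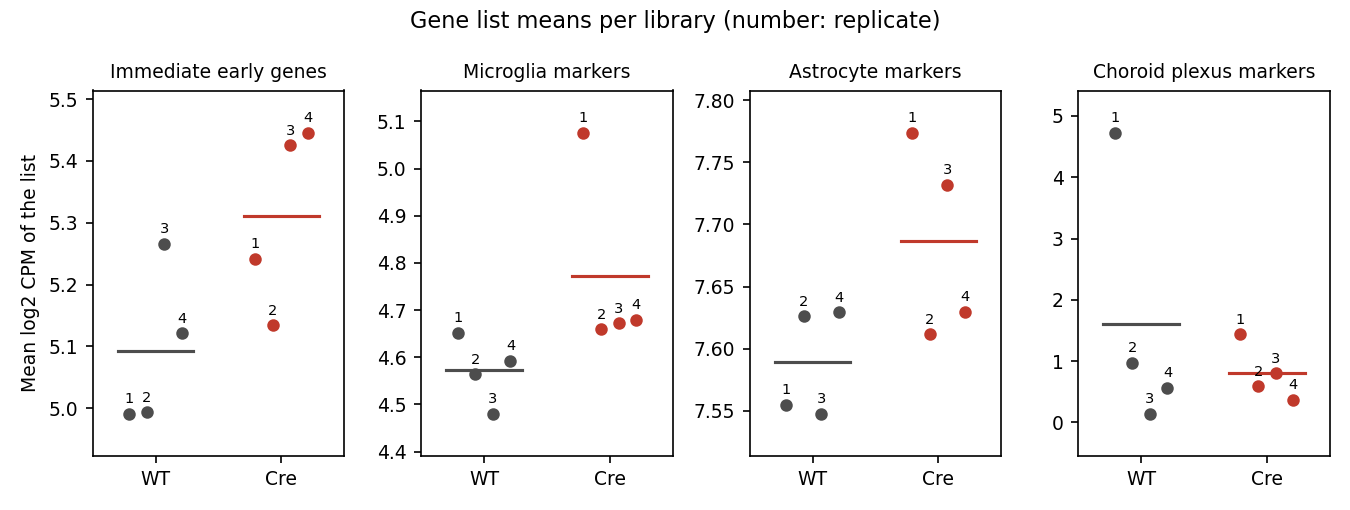
Mean log2 CPM over the members of 4 lists (vertical axes, which do not start at 0) in each WT and Cre library; points carry the replicate number and lines mark group means. Immediate early genes overlap between groups, microglia markers are highest in Cre replicate 1 at 5.08, and choroid plexus markers stand at 4.73 in WT replicate 1 alone.

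The other 23 lists did not pass by camera (adjusted p from 0.0767 to 0.961). Among markers of hippocampal neurons the median log2 fold changes were 0.01 for dentate granule neurons, -0.06 for CA1, -0.05 for CA2 and CA3, -0.01 for interneurons and -0.005 for parvalbumin interneurons. Markers of adjoining tissue had medians of 0.02 (thalamus and habenula), 0.03 (neocortex) and 0.09 (striatum). Further medians were 0.04 for reactive astrocytes, 0.06 for oligodendrocyte precursors, -0.01 for endothelial and mural cells, 0.15 for ependymal cells, -0.31 for meningeal fibroblasts and 0.06 for blood. Voltage-gated calcium channels (-0.02), calcium/calmodulin signalling (-0.02), GABA genes (-0.03), p53 targets (0.03), stress response (unfolded protein and heat shock, -0.02), interferon response (-0.002), mitochondrially encoded genes (0.08) and sex-linked genes (0.03) completed the set, with synaptotagmins above. Median and mean had opposite signs for the mitochondrial (mean -0.04), dentate granule (-0.01), endothelial (0.02) and blood (-0.01) lists. With an estimated correlation 0 of the 33 lists passed, and 1, the Camk2a neighbours, had an unadjusted p under 0.05; fry passed 2, the Camk2a neighbours and the synaptotagmins. Some lists passed by camera when 1 library was left out. Without WT replicate 2 these were CA2 and CA3 (adjusted p = 0.0340), endothelial and mural (0.0168), meningeal (0.0114) and blood markers (0.0340), with CA2 and CA3 lower and the others higher, meningeal markers thus turned from their direction with all libraries. Without WT replicate 4 p53 targets (adjusted p = 0.0397), striatal markers (0.0471) and the stress response (0.0477) were higher, the last against its direction with all libraries, and meningeal markers were lower (0.0397). Without WT replicate 3 meningeal markers were again lower (adjusted p = 0.0217). The remaining passes, each in its direction with all libraries, were mitochondrial genes without WT replicate 1 (adjusted p = 0.0248) or Cre replicate 1 (0.000941), GABA genes and striatal markers without Cre replicate 2 (0.0174 and 0.00556), and oligodendrocyte precursor markers without Cre replicate 4 (0.0248).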

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

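The test of other splits was chosen before its result was seen; the other tests of explanations in this part were chosen after the results were seen. The real split of the 8 libraries called 5 genes, and the highest of the other splits 3. Only 1 of the 35 splits, the real one, gave as many genes, which is the lowest share this test can reach with 8 libraries. It argues against chance for the count of called genes but cannot exclude it.

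The first pattern is the rise of Syt2, a gene strongly expressed by parvalbumin interneurons and by many neurons outside the hippocampus. More thalamic or habenular tissue in the Cre samples was taken to need a median log2 fold change of at least 1 in the thalamus and habenula list. That median was 0.0190 (SE over members 0.05). The same was asked of the parvalbumin interneuron list, whose median was -0.0047 (SE over members 0.03). Each SE treats genes, not libraries, as the units. Both medians argue against a shared rise of either list. They cannot exclude more of such tissue or cells if the list members are less restricted to them than Syt2, which was not tested. A rise shared by the neighbourhood is argued against by the other genes within 1 Mb of Syt2, with a median of -0.0052 (SE over genes 0.04). What also stays open is a hypothesis: Syt2 may be transcribed from additional or altered DNA carried with the transgene, or respond to the Cre protein, and neither was tested, since reads of the transgene or its insertion site were not analysed here.

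The second pattern is the rise of Arsi, Slc6a7 and Cdx1 around Camk2a. If the line carried extra copies of this segment, each transcribed like the resident copy, Slc6a7 and Arsi would rise by the same factor, and their log2 difference was -1.28 (SE 0.24). A rise reaching the next genes outward is argued against by the upper 95% limits of Tcof1 and Pdgfrb, at most 0.24. Reads running past the end of Camk2a cannot explain Arsi, which ends 7.06 kb before Camk2a begins on the same strand. Slc6a7 lies 7.23 kb past that end and faces it. Because the strand setting is not given, such reads cannot be told apart from its own transcripts. The gain of 239 CPM would be 5.13% of the Camk2a level. Camk2a was level between the groups (4652 ± 120 CPM in WT, 4669 ± 149 in Cre). All Slc6a7 reads in WT came to 72.7 ± 4.72 CPM. These values argue against reads running on at the same rate per Camk2a transcript in both groups. A higher rate in Cre alone was not tested. A candidate explanation that stays open, as a hypothesis, is extra copies of a segment of about this extent in the transgene, transcribed at other levels than the resident genes and with at most 4.96% more Camk2a transcript, which DNA copy number or reads across transgene junctions would test and which was not tested here.

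The third pattern is Mcm6, which fell, and Pm20d1, higher without passing, both on chromosome 1 before Syt2. A change carried by 1 library is argued against by the fold sizes without each library in turn, -0.79 to -0.66 for Mcm6 and 1.03 to 1.38 for Pm20d1 on the log2 scale, each at least 4.56 standard errors from 0, although the Mcm6 call itself was lost in 4 of those fits (adjusted p from 0.0777 to 0.125, without WT replicate 1 or Cre replicate 1, 2 or 3). Both genes were picked for their change in these same libraries, which favours such an outcome. A linked segment of other DNA around Syt2 may bring several changed genes, and within 10 Mb 7 of 120 other genes (5.83%, exact interval 2.38% to 11.6%) had an unadjusted p under 0.05 against 515 of 14938 elsewhere (3.45%; Fisher's exact p = 0.200). Chromosome 1 had the highest such share of the 20 chromosomes compared without Syt2, Mcm6 and Pm20d1, 54 of 970 genes (5.57%; Fisher's exact adjusted p = 0.0105), of which 47 of 850 lay beyond that window (5.53%), and chromosome 3 followed with 41 of 759 (adjusted p = 0.0562) and 0 called genes. The share thus does not single out the window within chromosome 1, neighbouring genes are not independent, and a linked segment and separate changes cannot be told apart here with 120 genes. By chance alone a share of 0.05 would reach such a p. Over all tested genes 555 did, where 793 would by chance alone. The shares of chromosome 1 and of the window thus lie near the chance level, above a rest that lies below it.

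In 9 of 148 groups of 4 libraries, 1 library lay apart from the other 3, where chance gives about 7.4. The values are the gap to the nearest library as a share of the range of the group, on the log2 CPM scale. Cre replicate 1 stood apart for Ctss (0.917), Gfap (0.845), the reactive astrocyte markers (0.933) and the microglia markers (0.952), each time as the highest Cre library. Ctss is a member of the microglia list and Gfap of the reactive astrocyte list, so these flags are not independent. WT replicate 1 stood apart for Clic6 (0.831, highest) and Ppp1r12b (0.831, lowest). WT replicate 2 stood apart for Cdx1 (1, as the single WT library with a count) and for CA2 and CA3 markers (0.857, lowest). Cre replicate 4 was lowest for the sex-linked genes (0.851).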

How the results depend on the processing

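Of the alternatives, the edgeR exact test, summed symbols and the 10 Mb window were chosen after the data were seen. Syt2 (log2 fold change 2.28 to 2.40), Slc6a7 (2.06 to 2.14) and Arsi (3.18 to 3.52) passed under every alternative. Cdx1 passed wherever it was tested (5.002 to 7.36), and the filter of CPM 1 in 4 libraries left it untested. The count of called genes was 4 to 7, against 5. DESeq2 and the exact test each added Pm20d1 and Hes5, the fit with no filter added Pm20d1 and Malat1, and leaving out WT replicate 2 added Col6a4. Genes lower in Cre numbered 1, but 2 with DESeq2 and the exact test (Mcm6 and Hes5), 0 against a minimum fold of 1.2, and 0 to 1 without 1 library. Values near 0 changed sign without 1 library: Camk2a ranged from -0.0115 to 0.0191, Tcof1 from -0.0010 to 0.0719 and Pdgfrb from -0.0879 to 0.0826, with -0.00075 for Pdgfrb without a filter. Ttr ranged from -5.89 to 0.39 and Clic6 from -3.46 to 0.67, the upper values without WT replicate 1. Of the 15 gene lists, 6 passed, but 2 to 7 without 1 library (2 without Cre replicate 3, 3 without WT replicate 3), 0 with an estimated correlation and 2 with fry. Of the 18 marker lists, 4 passed, but 2 to 8 without 1 library (2 without WT replicate 1, 8 without WT replicate 2), 0 with an estimated correlation and 0 with fry. Fits without 1 library also hold fewer libraries, and the cause of these differences was not tested. The replicate numbers did not pair the libraries: same-numbered libraries deviated from their group means with correlations of 0.26, -0.11, 0.04 and 0.12, and of the Cre libraries only replicate 1 correlated best with its own number. With the number as a replicate block, 6 genes passed, the 5 and Fos (0.56, adjusted p = 0.0112 by edgeR, 0.0112 to 0.9999998 over its alternatives), and the vesicle release and glutamate receptor lists did not (adjusted p = 0.106 and 0.0577). Scaling moved the median of all genes by less than 0.01. Depth limits the fold of Cdx1, with 1 count in WT.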

Other observations

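Hippocampal cell identity genes moved little between the groups. Markers of dentate granule, CA1, CA2 and CA3 neurons and interneurons had medians between -0.06 and 0.01 on the log2 scale, and their lists did not pass by camera (adjusted p from 0.346 to 0.961), although CA2 and CA3 markers did without WT replicate 2 (adjusted p = 0.0340). The gain of Syt2 transcript was 141 CPM (SE 6.43), which brought it to 176 CPM, against 1427 CPM for Syt1 in the same libraries. Without a correction for transcript length, these levels do not give the ratio of both transcripts. Slc6a7 and Syt2 rose by factors whose log2 difference was -0.21 (SE 0.09), which did not pass an exact permutation test (p = 0.0857, n = 4 per group), while Arsi rose by 1.07 more than Syt2 on that scale (SE 0.24; exact permutation p = 0.0286, the smallest possible).

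All 8 libraries carried transcripts of the Y chromosome, with 1466 to 2009 counts of Ddx3y, and 0 to 5 counts of Xist. The first principal component of log2 CPM took 27.2% of the variance and set Cre replicate 1 (-18.4) and WT replicate 1 (-12.3) at one end and Cre replicate 4 (15.2) at the other, so it did not follow genotype.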
